A study of Drosophila melanogaster with 21 samples.

How the data were processed

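Polyadenylated RNA of adult fly heads was sequenced after ad libitum feeding or 16 hours of fasting. The flies were 3 to 5 days old, and the libraries were made with a NEBNext Ultra kit, per the labels' protocols. Control flies are given as w1118, a stock named for a mutation in the eye-colour gene white, and knockout flies as lacking Crtc, the fly's CREB-regulated transcription coactivator. The series has 21 samples, of which 10 head libraries enter the tables used here: 3 fed and 2 fasted control libraries, and 3 fed and 2 fasted Crtc knockout libraries. The tables' names number these libraries otherwise than the labels do, which was taken as a renumbering that leaves out the CREB mutant heads, since the labels' numbers would put control libraries into the knockout table. The Crtc base mean of 0.36 in the authors' deposited table of knockout fasting leaves no room for such libraries, while the membership of the control libraries could not be checked in this way. Samples of CREB mutant heads (4), a Sik2 mutant head (1) and bodies (6) are not analysed here. The labels list the third fed library of each genotype with another set of samples than the first and second, and that set has no fasted library. Without values per library, a difference between sets could not be taken out of the deposited fasting comparisons. The labels do not say whether replicates came from separate groups of flies, so p-values measure the spread between these libraries, which may be technical.

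The submitters' processing notes name TopHat2, STAR, Cuffdiff and DESeq2 and the fly builds dm3 and dm6, with no versions and no roles. Which aligner and build lie behind the tables is not given in the sources used here, nor is whether reads were counted by strand. Per the file headers, each of the 4 deposited tables gives a base mean, a signal averaged over all libraries of the comparison, and no value per library. The authors' log2 fold changes come with standard errors, also deposited on the log2 scale. A Wald score per gene was deposited as well, and it equals the fold over its standard error within 2.7e-07. The deposited p-values follow from that score, and the adjusted p-values are missing for genes the authors' DESeq2 run left out of its adjustment. The standard errors have a ceiling of 0.285, 0.315, 0.359 and 0.288 (control fasting, knockout fasting, fasted knockout against control, fed knockout against control) and fall again at low counts, the form that DESeq2's normal prior on the folds gives in the authors' tables. The printed folds are therefore shrunken towards 0, most strongly for genes with few reads. The central spread of the Wald scores was 0.741 to 0.795 of a standard normal in the authors' deposited tables, so their p-values are on the large side for most genes.

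Each table lists 17559 FlyBase identifiers, of which 17253 were given a symbol from an Ensembl name table and 306 were not. The tables hold no coordinates. Positions in the text are 1-based and come from the Ensembl release 115 annotation of BDGP6.54, and were used only to say where a gene lies. Depth per library is unknown. The base means sum to 4087577, 3572598, 4405826 and 3465010 normalized counts per library, in the order above. Counting error per gene is therefore part of the authors' standard errors and no separate interval was made.

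A gene was called at an adjusted p under 0.05 as deposited. The difference of the fasting response was computed per gene as the log2 fold in knockout minus that in control heads, over the root of the sum of both squared standard errors, with a two-sided normal p and Benjamini-Hochberg adjustment over genes with a base mean of at least 10 in both tables. Those 2 tables share no library, and neither do the 2 tables of knockout against control. Overlaps of calls were tested with Fisher's exact test, one-sided. On simulated data with the real standard errors of 8474 genes, normal errors and 100 genes changed by each size, the difference test recovered 44.0% of genes changed by 1 on the log2 scale and 99.0% of those changed by 2, and 5.9% of its calls were unchanged genes. The simulation took the standard errors as known, so that share does not measure the false share among the real calls.

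Gene lists were tested with cameraPR of limma 3.58.1 (R 4.3.3) on the Wald scores, two-sided, with a preset correlation of 0.01. P-values were adjusted over 112 tests (28 lists in 4 comparisons), and separately over the 26 lists with at least 5 members tested for the difference. Which calls would hold with an estimated correlation could not be computed, since the tables hold no values per library. The lists were one-carbon metabolism, insulin and TOR signalling, lipolysis and beta-oxidation, lipid synthesis, sugar and glycogen metabolism, digestive enzymes, amino acid catabolism, autophagy and lysosome, ribosome biogenesis, cytosolic ribosomal proteins, oxidative phosphorylation, V-ATPase, antimicrobial immunity, heat shock, detoxification, circadian clock, phototransduction, neuropeptides, odorant-binding proteins, ecdysone and juvenile hormone, genes tied to Crtc activity, eye pigment, and markers of neurons, glia, fat body, muscle, female and male reproductive tissue. Lists, tests, alternatives and the rule for named genes were fixed before the data were examined, while the tests of other causes were partly chosen later, as stated beside them. Of the list names, 28 could not be matched to an identifier of the tables, among them InR, S6k, FASN1 and the antimicrobial list's Drs. One name of the one-carbon list, CG5802, resolved to meigo, which is not an enzyme of that pathway and was kept because the list was fixed.

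Crtc, CrebB, Sik2, Sik3 and w are named throughout. Other named genes are drawn from the 8 called genes with the highest and the 8 with the lowest fold in each table at a base mean of at least 20, up to 3 called members per list and direction, and the 8 highest and 8 lowest called differences. One-carbon and insulin pathway members are given as groups with examples. Genes chosen otherwise are said to be so. Alternatives were other thresholds (0.01, 0.1 and a minimum absolute log2 fold of 1), adjustment over every gene with a p-value, a base mean of at least 50, Wald scores rescaled to their central spread, folds shifted to a median of 0, a t distribution with 6 degrees of freedom for the difference, the other pair of tables for the difference, and, for lists, a correlation of 0.05, ranks or folds. Unshrunken folds, solved from the Wald score, the standard error and its ceiling for genes with a base mean of at least 50 and a standard error of at least 0.1, were added after seeing the data. So was the minimum fold at that base mean. Scripts ran in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.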

Results

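Gene expression was compared in heads of control (w1118) and Crtc knockout flies that were fed or had been fasted for 16 hours. Crtc encodes a coactivator of the transcription factor CREB. The series title names starvation resistance, one-carbon metabolism and insulin signalling as the study's subject. Control heads gave 3 fed and 2 fasted libraries, and knockout heads gave 3 fed and 2 fasted libraries. All folds below are shrunken log2 folds with their standard errors from the authors' comparisons, and adjusted p-values of single genes in 1 table are those of the authors' DESeq2 run.

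The targeted gene was read first, since it checks the genotype labels. Crtc (FBgn0036746, chromosome 3L, 17659818 to 17669234, minus strand, protein-coding) was lower in knockout than in control heads by -4.88 ± 0.32 when fasted and -4.48 ± 0.26 when fed in the authors' deposited tables (adjusted p = 5.32e-50 and 1.11e-63). Its base mean over the knockout libraries was 0.36 in the authors' deposited table of knockout fasting, against 339.7 over the control libraries in their table of control fasting. Fasting left Crtc at 0.02 ± 0.19 in control heads in the authors' deposited table (adjusted p = 0.998). CrebB, the fly's CREB gene, and the salt-inducible kinase genes Sik2 and Sik3, whose products act on Crtc, were called in none of the authors' deposited tables, with folds between -0.24 and 0.14. The eye pigment transporter gene w was lower in knockout heads by -2.31 ± 0.34 when fasted and -2.42 ± 0.27 when fed in the authors' deposited tables (adjusted p = 8.16e-10 and 1.48e-16). Its base mean was 80.14 over the control libraries and 4.935 over the knockout libraries in the authors' deposited fasting tables. The stock named for a white mutation thus held more of the transcript.

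In fasted control heads the lists of one-carbon metabolism and of lipolysis and beta-oxidation stood higher than other genes, and muscle markers stood lower. The lipase gene CG5966 rose by 4.33 ± 0.18, the cytochrome P450 gene Cyp4e3 by 3.59 ± 0.19 and the lipase gene mag by 2.96 ± 0.28 in the authors' deposited table of control fasting. The annotated mag lies within atk on the opposite strand, and overlapping reads may count for either. Pfas, CG11089 and Gart, which encode enzymes of de novo purine synthesis, rose by 3.16 ± 0.15, 3.14 ± 0.16 and 2.94 ± 0.17 in the same authors' deposited table. The sharpest fall was that of fit, a satiety peptide gene, at -3.58 ± 0.27, followed by Root at -2.28 ± 0.25 and Gbs-70E, a glycogen-targeting phosphatase subunit, at -1.92 ± 0.20 in the authors' deposited table. The larval storage protein genes Lsp2 and Lsp1beta fell, with folds of -1.64 ± 0.28 and -1.63 ± 0.17 in the authors' deposited table.

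One-carbon metabolism, the folate and methionine cycle enzymes that supply methyl groups and purine carbons, had 11 of 25 measured members up in fasted control heads, 0 down and 14 not called. Adjusted over the list alone, 12 were up and 1 was down, and the list stood above other genes (camera, adjusted p = 3.82e-40). Nmdmc rose by 1.99 ± 0.16, Shmt by 1.96 ± 0.21 and Ahcy by 1.95 ± 0.22 in the authors' deposited table. The annotated Rel gene lies within Nmdmc on the same strand and rose too, by 0.81 ± 0.17 in the authors' deposited table. Overlapping reads may count for either, here and in the Nmdmc values below. Insulin and TOR signalling had 4 of 30 members up, 1 down and 25 not called (adjusted over the list alone, 5 and 2), with camera adjusted p = 0.00346. Among the risen members, Lst, which restrains insulin secretion, rose by 1.98 ± 0.20, the translation inhibitor Thor by 1.38 ± 0.17 and the insulin-binding protein gene ImpL2 by 1.13 ± 0.19 in the authors' deposited table. The glucosidase gene tobi, a target of insulin-producing cells, fell at -1.29 ± 0.22 in the authors' deposited table. The insulin list was no longer past the threshold with a preset correlation of 0.05 (adjusted p = 0.0558) or on ranks (adjusted p = 0.252).

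Lipolysis and beta-oxidation had 14 of 23 members up, 1 down and 8 not called in control heads (adjusted over the list alone, 15 and 1), with camera adjusted p = 2e-47. The brummer lipase gene bmm rose by 2.08 ± 0.16, while the lipid droplet gene Lsd-1 fell at -0.85 ± 0.24 in the authors' deposited table. Detoxification genes were up for 10 of 36 members and down for 0 (adjusted over the list alone, 11 and 1), with camera adjusted p = 4.26e-15. Amino acid catabolism had 4 of 19 members up and 0 down (adjusted over the list alone, 7 and 0), with camera adjusted p = 1.32e-05. Digestive enzymes had 3 of 21 up and 0 down, and the same adjusted over the list alone, with camera adjusted p = 3.6e-06, a call lost on ranks (adjusted p = 0.164). Those 3 were Mal-B2 at 2.59 ± 0.18 and the neighbouring amylase copies Amy-p at 2.17 ± 0.20 and Amy-d at 1.07 ± 0.17 in the authors' deposited table, and reads of the near-identical amylase genes may have been shared between them. Autophagy and lysosome genes had 2 of 24 up and 0 down (adjusted over the list alone, 4 and 0), with camera adjusted p = 4.93e-05. Cytosolic ribosomal proteins had 0 of 81 members called, and 0 adjusted over the list alone, yet 79 lay above 0 with a median of 0.29 (camera, adjusted p = 3e-14).

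Markers of other head tissues moved in the same comparison. Muscle markers had 0 of 17 members up and 5 down (adjusted over the list alone, 0 and 10), with camera adjusted p = 3.84e-13. The myosin genes Mlc2 and Mhc fell, at -0.96 ± 0.16 and -0.71 ± 0.17 in the authors' deposited table. Fat body markers had 2 of 16 up and 5 down (adjusted over the list alone, 2 and 8; camera adjusted p = 1.51e-06), and glial markers had 1 of 12 up and 3 down (adjusted over the list alone, 1 and 6; camera adjusted p = 0.000185). Neuronal markers had 0 of 18 called, and 0 adjusted over the list alone, with a median of -0.23 (camera adjusted p = 0.008, and 0.0537 with a correlation of 0.05). Antimicrobial immunity had 1 of 42 members up and 5 down (adjusted over the list alone, 2 and 8; camera adjusted p = 1.12e-06), with TotX at -1.44 ± 0.25 and PGRP-SB1 at -1.42 ± 0.23 in the authors' deposited table.

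In all, 205 genes rose and 154 fell among 9361 genes with an adjusted p in the authors' deposited table of control fasting. Of these 359 genes, 145 had an absolute log2 fold of at least 1.

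In fasted knockout heads the lists of lipolysis and beta-oxidation and of one-carbon metabolism stood higher than other genes as well. Cyp4e3 rose by 6.73 ± 0.19, CG5966 by 5.06 ± 0.23 and the gluconeogenic enzyme gene Pepck2 by 3.99 ± 0.18 in the authors' deposited table of knockout fasting. The transaminase gene Bcat rose by 3.22 ± 0.20, the serpin gene Spn88Eb by 2.87 ± 0.26 and the purine synthesis gene CG11089 by 2.87 ± 0.19 in the authors' deposited table. The falls were led by phu at -2.60 ± 0.30, Root at -1.97 ± 0.27, CG15282 at -1.97 ± 0.28 and Lsp2 at -1.81 ± 0.23 in the authors' deposited table.

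One-carbon metabolism had 9 of 25 members up, 0 down and 16 not called in knockout heads (adjusted over the list alone, 10 and 0), with camera adjusted p = 4.06e-21. Nmdmc rose by 2.41 ± 0.23, the phosphoserine phosphatase gene aay by 2.33 ± 0.16 and CG11899 by 1.56 ± 0.27 in the authors' deposited table. Insulin and TOR signalling had 3 of 30 up and 1 down (adjusted over the list alone, 4 and 2), and the list did not pass (camera adjusted p = 0.112). Thor rose by 2.30 ± 0.17, the insulin-like peptide gene Ilp6 by 1.06 ± 0.24 and the sestrin gene Sesn by 0.86 ± 0.18, and the insulin-like peptide gene Ilp5 fell at -1.32 ± 0.30 in the authors' deposited table. Lst stood at 0.13 ± 0.27 and ImpL2 at -0.45 ± 0.21, neither called in the authors' deposited table (adjusted p = 0.998 and 0.454).

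Lipolysis and beta-oxidation had 15 of 23 members up and 0 down in knockout heads (adjusted over the list alone, 18 and 0), with camera adjusted p = 1.08e-73. The acyl-CoA dehydrogenase gene Mcad is a further member outside the naming rule, chosen after its values were seen, and rose by 2.01 ± 0.28 in the authors' deposited table. Detoxification had 11 of 36 up and 0 down (adjusted over the list alone, 16 and 0; camera adjusted p = 4.19e-34), and amino acid catabolism had 7 of 20 up and 0 down (adjusted over the list alone, 7 and 0; camera adjusted p = 1.9e-08). Sugar and glycogen metabolism had 4 of 28 up and 0 down (adjusted over the list alone, 7 and 0; camera adjusted p = 2.42e-12), against 6 up and 1 down in control heads, where the list did not pass (adjusted over the list alone, 6 and 5; camera adjusted p = 0.109, and 0.0245 on folds). Heat shock genes had 2 of 17 up and 0 down (adjusted over the list alone, 5 and 0; camera adjusted p = 0.00021), with Hsp26 at 1.38 ± 0.29 and Hsp68 at 1.21 ± 0.21 in the authors' deposited table. Lipid synthesis had 5 of 18 up and 0 down (adjusted over the list alone, 5 and 2; camera adjusted p = 0.00945), a call lost with a correlation of 0.05 (adjusted p = 0.0577), on ranks (adjusted p = 0.26) and at a base mean of at least 50 (adjusted p = 0.0781). In control heads this list passed too, with 3 of 18 up and 0 down (adjusted over the list alone, 5 and 0, with camera adjusted p = 0.00106). Muscle markers had 0 of 18 called, and 0 adjusted over the list alone (camera adjusted p = 0.859), and fat body markers had 1 of 17 up and 3 down (adjusted over the list alone, 2 and 3; camera adjusted p = 0.863). Neuronal markers had 0 of 18 called, and 0 adjusted over the list alone, with a median of -0.31 (camera adjusted p = 0.000299). Glial markers had 3 of 12 up and 0 down (adjusted over the list alone, 3 and 1, with camera adjusted p = 0.271). Among ribosomal proteins 0 of 82 were called, with a median of 0.30 (camera adjusted p = 3.05e-09).

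In knockout heads 277 genes rose and 50 fell among 10037 with an adjusted p in the authors' deposited table. Of these 327 genes, 181 had an absolute log2 fold of at least 1.

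The responses of both genotypes overlapped. Among 8474 genes with a base mean of at least 10 and an adjusted p in both tables, 121 of the 198 that rose in control heads (61.1%) also rose in knockout heads, where independent lists would share 6.19 (Fisher's exact test, p = 4.59e-141), and 29 of the 151 that fell (19.2%) fell in both, against 0.82 (p = 1.54e-40). In knockout heads 265 of these genes rose and 46 fell. Across genes, which are not independent replicates, the folds correlated with Pearson's r of 0.619 and Spearman's rho of 0.493. The Bomanin genes BomBc2 and BomS1, secreted immune peptides, fell in control and rose in knockout heads. At a threshold of 0.01 the genes that fell in both numbered 10.

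Pfas, Adsl, Sardh, Lst and ImpL2 rose in fasted control heads and were not called in fasted knockout heads, and their responses differed between the genotypes. A larger set of genes had a more positive response in knockout heads. The difference (knockout minus control) was -2.60 ± 0.26 for Pfas (chromosome 2L, 6041181 to 6046050), whose response was 3.16 ± 0.15 in control and 0.56 ± 0.21 in knockout heads in the authors' deposited tables. For Lst the difference was -1.85 ± 0.34, for ImpL2 -1.58 ± 0.28, for the sarcosine dehydrogenase gene Sardh -1.42 ± 0.35 and for the purine enzyme gene Adsl -1.38 ± 0.30. The call of Sardh was lost with unshrunken folds, at a difference of -1.46. TotC, Usp8 and CG11425 followed at -1.35 ± 0.37, -1.27 ± 0.24 and -1.27 ± 0.35. The calls of TotC and CG11425 were lost with no filter on low counts. On the other side stood the identifier FBgn0010381, which has no symbol in the name table and so could enter no gene list, at 4.07 ± 0.35, Cyp4e3 at 3.14 ± 0.27, CG43402 at 2.69 ± 0.39 and fit at 2.15 ± 0.38. Whether FBgn0010381 is an older identifier of an unmatched list gene was not checked. One such gene is Drs of the antimicrobial list, whose counts therefore leave Drs out. The Bomanin genes BomT2 and BomS1 differed by 2.10 ± 0.34 and 1.92 ± 0.29, the nutrient-responsive peptide gene CCHa2 by 2.03 ± 0.30 and Achl by 1.96 ± 0.25.

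The difference passed for 59 genes in the positive direction and 9 in the negative, of 8474. These calls rest on a normal reference, and with a t distribution with 6 degrees of freedom 0 genes passed (190 at an unadjusted p under 0.05, smallest adjusted p = 0.108). Among the 59, 24 rose in knockout heads and were not called in control heads, 22 fell in control heads and were not called in knockout heads, and 7 rose in both. Among the 9, 6 rose in control heads and were not called in knockout heads. As a list, one-carbon metabolism did not differ between genotypes past the threshold (camera adjusted p = 0.329), with 0 of 24 members positive, Sardh negative and 23 not called, and 3 and 4 adjusted over the list alone. Gnmt, whose product methylates glycine to sarcosine, differed by -1.07 ± 0.35 and pug by -1.03 ± 0.36, neither past the threshold (adjusted p = 0.171 and 0.291). Insulin and TOR signalling had Thor and Ilp6 positive, at 0.92 ± 0.24 and 1.29 ± 0.32, and Lst and ImpL2 negative, among 25 members (2 and 2 adjusted over the list alone; camera adjusted p = 0.115). Lipolysis and beta-oxidation differed as a list (camera adjusted p = 6.49e-09), with 2 of 21 members positive and 0 negative (4 and 0 adjusted over the list alone). Those 2 were Lsd-1, which is also on the fat body list, at 1.81 ± 0.39 and the adipokinetic hormone receptor gene AkhR at 1.27 ± 0.29. In fed knockout against control heads this list had 0 of 23 members higher and 2 lower (camera adjusted p = 0.0141, and 0.092 with a correlation of 0.05). In fasted heads it had 5 higher and 2 lower (camera adjusted p = 0.00106, direction up). The difference of this list therefore need not be a stronger induction alone, since its fed level was lower in knockouts.

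Fat body, glial and muscle markers were higher by this test. Phototransduction genes were lower, with a median difference of -0.19 and 0 of 28 members called (0 and 0 adjusted over the list alone; camera adjusted p = 4.76e-05). Neuronal markers had a median of -0.11 and 0 of 18 called (0 and 0 adjusted over the list alone; camera adjusted p = 0.164). Fat body markers had a median difference of 0.56, with 2 of 12 members positive and 0 negative (5 and 1 adjusted over the list alone; camera adjusted p = 7.33e-06). Glial markers had one of 0.33, with 1 of 12 positive and 0 negative (3 and 0 adjusted over the list alone; camera adjusted p = 1.27e-06). Muscle markers had a median of 0.52, with 1 of 15 positive and 0 negative (5 and 0 adjusted over the list alone; camera adjusted p = 1.03e-10). Of 14 muscle markers with a base mean of at least 100 in both tables, 14 were below 0 in fasted control heads and 6 in fasted knockout heads. No edgeR or similar interaction fit on counts was possible without values per library.

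**Figure D1:**
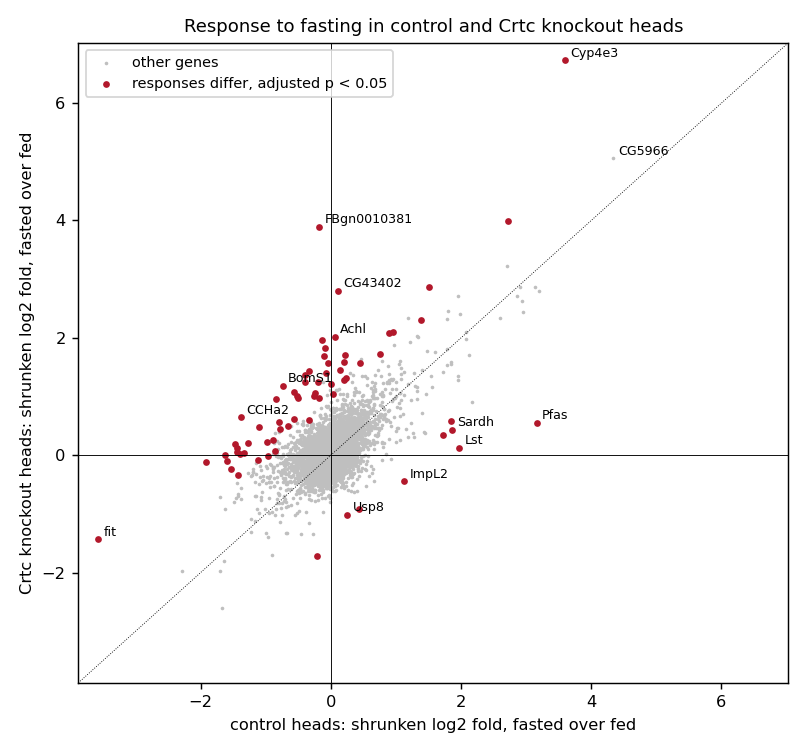
Shrunken log2 folds of fasting in control heads (x axis) and Crtc knockout heads (y axis) from the authors' deposited tables, 1 point per gene, with the 68 genes whose responses differed at an adjusted p under 0.05 in red and equal responses on the dotted line. Pfas, Lst and ImpL2 lie below the line, and Cyp4e3 and FBgn0010381 above it.

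**Figure D2:**
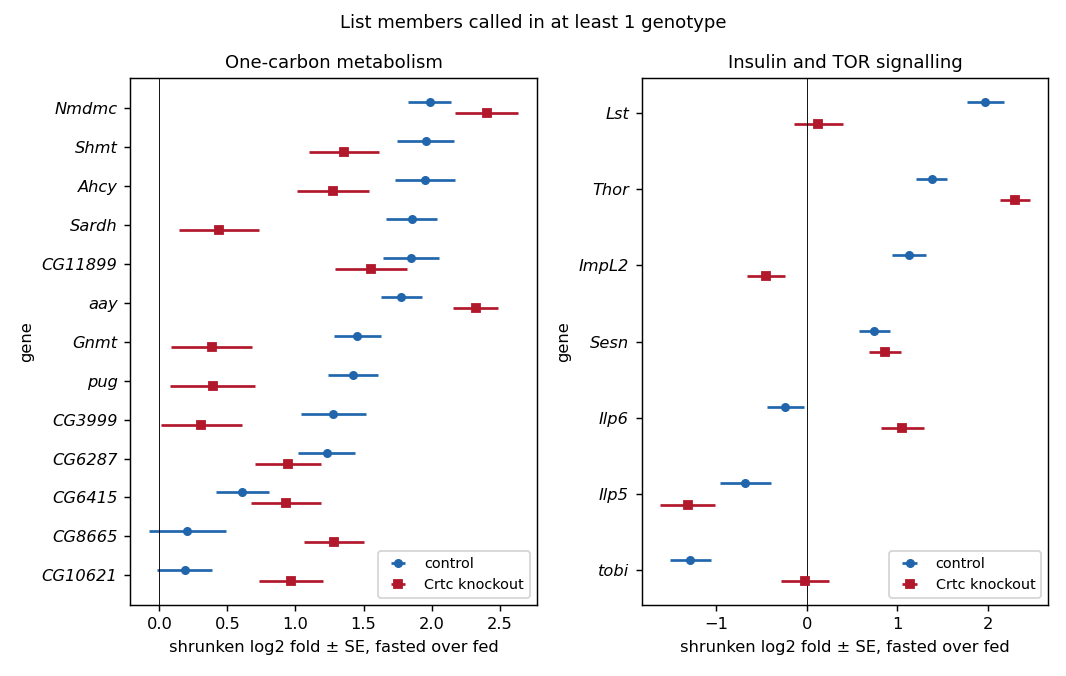
Shrunken log2 folds of fasting with standard errors (bars) in control (circles) and Crtc knockout heads (squares) from the authors' deposited tables, for list members called in at least 1 genotype. Sardh lies at 1.85 in control and 0.44 in knockout heads, and Lst at 1.98 and 0.13.

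Knockout and control heads were then compared within each feeding state. In fed heads the genes most reduced beside Crtc were Tektin-C at -4.33 ± 0.25, CG9150 at -4.16 ± 0.26, the odorant-binding protein gene Obp46a at -4.08 ± 0.26 and CG11426 at -3.89 ± 0.18 in the authors' deposited table of fed heads. Higher were CG31219 at 4.30 ± 0.26, the rhodopsin gene Rh6 (chromosome 3R, 15483158 to 15484699) at 3.85 ± 0.18 and CG8665 at 3.34 ± 0.24 in the authors' deposited table. The noncoding asRNA:CR45600 and CG6912, whose annotated ends overlap on chromosome 3R, were at 3.62 ± 0.26 and 3.05 ± 0.19 in the authors' deposited table, and overlapping reads may count for either. Pepck2 was at 2.97 ± 0.25, and tobi was lower at -2.99 ± 0.26 in the authors' deposited table.

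Phototransduction genes had 5 of 28 members higher and 2 lower in fed knockout heads (adjusted over the list alone, 8 and 2; camera adjusted p = 1.71e-12), among them Rh6, Rh5 at 1.06 ± 0.14 and Arr2 at 1.06 ± 0.14 in the authors' deposited table. Antimicrobial immunity had 2 of 42 higher and 9 lower (adjusted over the list alone, 2 and 11; camera adjusted p = 2.51e-14), with BomBc1 at -2.87 ± 0.24, TotM at -2.48 ± 0.28 and BomS1 at -2.02 ± 0.19 in the authors' deposited table. The Bomanin genes form a family with similar sequences, so reads may be split between its members. Circadian clock genes had 3 of 13 higher and 0 lower (adjusted over the list alone, 3 and 1; camera adjusted p = 0.000109), with tim at 1.69 ± 0.14, vri at 0.58 ± 0.15 and the clock neuron peptide gene Pdf at 0.53 ± 0.17 in the authors' deposited table. Glial markers had 1 of 12 higher and 3 lower (adjusted over the list alone, 1 and 5; camera adjusted p = 2.42e-06), with the astrocyte gene alrm at -1.32 ± 0.18 in the authors' deposited table. Digestive enzymes had 0 of 25 higher and 6 lower, and the same adjusted over the list alone (camera adjusted p = 0.000139), a call lost on ranks (adjusted p = 0.0907). Detoxification had 1 of 36 higher and 9 lower (adjusted over the list alone, 1 and 10; camera adjusted p = 0.0033), lost with a correlation of 0.05 (adjusted p = 0.0631) and on ranks (adjusted p = 0.121). One-carbon metabolism had CG8665 higher and Nmdmc lower, at -1.56 ± 0.18 in the authors' deposited table, of 25 members (1 and 1 adjusted over the list alone; camera adjusted p = 0.594). In fed heads 233 genes were higher and 256 lower in knockouts among 10285 with an adjusted p in the authors' deposited table, and 213 of these had an absolute log2 fold of at least 1.

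In fasted heads CG8665, a member of the one-carbon list, was higher in knockouts at 4.67 ± 0.24, CG31219 at 4.57 ± 0.33, Pepck2 at 4.11 ± 0.20 and CG10962 at 3.93 ± 0.27 in the authors' deposited table of fasted heads. Cyp4e3 stood at 3.60 ± 0.18, Rh6 at 3.55 ± 0.20 and CCHa2 at 3.38 ± 0.20 in the authors' deposited table. CG9150 was lower at -4.78 ± 0.30, Obp46a at -4.70 ± 0.32, Tektin-C at -4.54 ± 0.29, CG42876 at -4.36 ± 0.33 and CG11426 at -4.29 ± 0.21 in the authors' deposited table. One-carbon metabolism had 2 of 25 members higher and 6 lower (adjusted over the list alone, 4 and 7), and as a list did not pass (camera adjusted p = 0.439). Sardh was lower at -1.73 ± 0.23, Gnmt at -1.49 ± 0.20 and CG3999 at -1.33 ± 0.28, and CG10621 higher at 1.42 ± 0.21 in the authors' deposited table. Insulin and TOR signalling had 1 of 30 higher and 3 lower, and the same adjusted over the list alone (camera adjusted p = 0.0869), with ImpL2 at -2.06 ± 0.22, Lst at -1.84 ± 0.21 and tobi at -1.68 ± 0.35 in the authors' deposited table.

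Muscle markers had 11 of 17 members higher and 1 lower in fasted knockout heads (adjusted over the list alone, 13 and 1; camera adjusted p = 9.71e-10). In fed heads they had 3 of 18 higher and 1 lower (adjusted over the list alone, 3 and 1; camera adjusted p = 0.161). Act88F was at 1.47 ± 0.36, sls at 0.89 ± 0.21 and TpnC41C at -1.27 ± 0.34 in the authors' deposited table of fasted heads. Fat body markers had 5 of 17 higher and 1 lower (adjusted over the list alone, 5 and 2; camera adjusted p = 0.000546), with Lsd-1 at 2.79 ± 0.23, Lsp1beta at 1.93 ± 0.20 and Desat1 at -1.44 ± 0.19 in the authors' deposited table, and on ranks this list did not pass (adjusted p = 0.254). Neuropeptide genes had 3 of 30 higher and 0 lower (adjusted over the list alone, 4 and 1), and the list did not pass (camera adjusted p = 0.181, direction up). The 3 were CCHa2, Nplp3 at 2.00 ± 0.19 and Nplp4 at 1.48 ± 0.36 in the authors' deposited table. On ranks the list passed (camera adjusted p = 0.0495). With 8 of 30 members above 0 and a median of -0.16, that pass does not speak for higher expression. In fasted heads 340 genes were higher and 195 lower among 9917 with an adjusted p in the authors' deposited table, and 286 of these had an absolute log2 fold of at least 1.

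The effects of the knockout overlapped between the states. Among 8556 genes with a base mean of at least 10 and an adjusted p in both tables, 113 of the 207 higher in fed heads (54.6%) were also higher in fasted heads, where independent lists would share 7.89 (Fisher's exact test, p = 9.93e-111), and 119 of the 242 lower in fed heads (49.2%) were lower in both, against 5.2 (p = 9.58e-150), with Pearson's r of 0.719 and Spearman's rho of 0.542 across 8557 genes. In fasted heads 326 of these genes were higher and 184 lower. Called in opposite directions were BomT2, CG31689, CG34134, FBgn0010381 and fit.

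**Figure D3:**
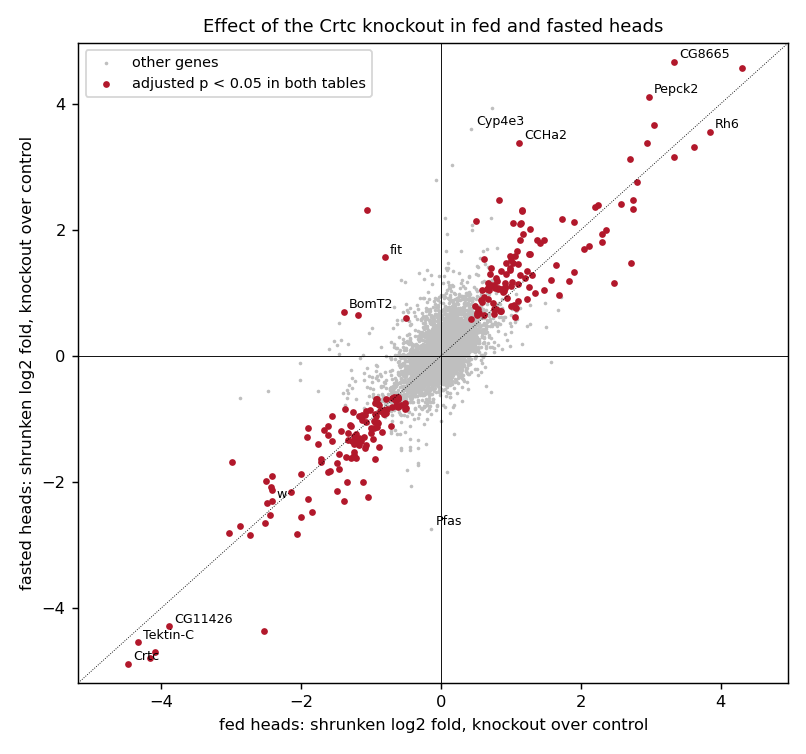
Shrunken log2 folds of Crtc knockout over control in fed heads (x axis) and fasted heads (y axis) from the authors' deposited tables, 1 point per gene, with genes at an adjusted p under 0.05 in both tables in red and equal effects on the dotted line. Tektin-C, CG11426 and Rh6 lie near the line, while Pfas is lower in fasted heads alone, at -2.74.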

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

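The tests of sex ratio, fat body content and shares of other tissues were chosen only after the results were seen, and the tests of the chromosomal region and the time of day before. The bounds for shrinkage were written before that test was run, but it uses the unshrunken folds, which were added after seeing the data. The fasting response differed between genotypes for 68 genes by a test of the difference itself. Positive differences (knockout minus control) were 4.07 for FBgn0010381, 3.14 for Cyp4e3, 2.69 for CG43402, 2.15 for fit, 2.10 for BomT2, 2.03 for CCHa2, 1.96 for Achl and 1.92 for BomS1. Negative ones were -2.60 for Pfas, -1.85 for Lst, -1.58 for ImpL2, -1.42 for Sardh, -1.38 for Adsl, -1.35 for TotC, -1.27 for Usp8 and -1.27 for CG11425. Lists that differed by camera had median differences of 0.44 for lipolysis and beta-oxidation, 0.29 for sugar and glycogen metabolism, 0.24 for antimicrobial immunity, 0.33 for glial markers, 0.56 for fat body markers, 0.52 for muscle markers, 0.25 for detoxification, 0.32 for heat shock, 0.29 for odorant-binding proteins, -0.19 for phototransduction and -0.089 for genes tied to Crtc activity, a call lost with a correlation of 0.05 (adjusted p = 0.117) and on ranks (adjusted p = 0.071), with 0 of 15 members called. On ranks oxidative phosphorylation (adjusted p = 5.57e-05) and neuropeptides (adjusted p = 0.000401) passed as well, with 60 of 65 and 4 of 24 members above 0.

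For these differences, shrinkage with another prior in each table would have undone most calls once removed, but 59 of 63 genes (93.7%) with a base mean of at least 50 were called again in the same direction with unshrunken folds, at a median size 1.16 times the shrunken one. Unshrunken folds keep each gene's Wald score in each table by construction, and genes with fewer reads were left out. A high share was therefore likely beforehand, and the test does not exclude shrinkage. More fat body tissue in the fasted knockout libraries could add to the positive differences: the fat body list's median was 0.107 in fasted and -0.133 in fed heads (knockout against control), a gap of 0.241, short of the 0.5 set for it, and 2 of 4 abundant members lay at or below 0 where 3 were set to exclude it, so it stays open. The median member in fasted heads, Fbp1, has a base mean of 1.08 and decides little. A smaller share of every non-neuronal tissue in the fasted control libraries may explain why muscle, fat body and glial lists had median differences of 0.522, 0.563 and 0.331, but 9 fat body members with a base mean of at least 100 spread over an interquartile range of 0.564 log2 (0.309 to 0.873), too wide to count as moving alike and too narrow to exclude it. Such a share would raise neuronal markers in fasted control heads, where their median was -0.23. It was -0.31 in fasted knockout heads, and the median difference of -0.11 did not pass (camera adjusted p = 0.164), so these markers do not decide it. Pfas, Lst and ImpL2 moved in the other direction from these tissues, but which head cells express them is not given here. A loss of Crtc-dependent induction is the biological hypothesis the design names. For neither direction was it separated from the tissue shares or from a difference of stock between control and knockout flies.

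The effects of the knockout overlapped between fed and fasted heads. A chromosomal region around Crtc carried over from the original stock would place such genes near it: 23 of 239 genes called alike (9.6%) lay within 5 Mb of Crtc against 765 of 9639 genes with an adjusted p in both tables at any base mean (7.9%), with an odds ratio of 1.24 (95% interval 0.77 to 1.93, Fisher's exact p = 0.331), which neither shows nor excludes an excess. Another sex ratio could contribute too, but 0 of Yp1, Yp2, Yp3, roX1 and roX2 were called in the authors' deposited tables of knockout against control, and the higher of their 2 median absolute folds was 0.264, just over the 0.25 set to exclude it, with Yp1 and Yp2 at base means under 5. Yp1, Yp2 and Yp3 lay at 0.35, 0.12 and 0.26 and roX1 and roX2 at -0.16 and -0.54 in fasted heads, and at 0.63, 0.21, 0.54, 0.002 and -0.22 in fed heads, in the authors' deposited tables, signs that this explanation would give in all but roX1 in fed heads. At such counts the signs of Yp1 and Yp2 decide little. The male dosage compensation RNA roX1 had base means of 9166 in fasted and 8744 in fed heads in the authors' deposited tables. These signs do not show another sex ratio, which stays open. The lower w in knockout heads (base mean 4.935, against 80.14 in control heads, in the authors' deposited fasting tables) may likewise mark a difference of stock rather than of Crtc, which these libraries cannot separate. Why the control named for a white mutation holds more w was not tested.

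The fasting responses overlapped between genotypes: 121 genes rose in both, of 198 in control and 265 in knockout heads, and 29 fell in both, of 151 and 46, with the same sign for 88.8% of control and 90.7% of knockout calls. Another time of day for fasted than for fed flies could produce part of it, and would move per, tim and vri against Clk. Of these 4, 0 were called in either of the authors' deposited fasting tables, with median absolute folds of 0.299 in control and 0.411 in knockout heads, above the 0.25 that would have excluded it. In the authors' deposited tables per, tim and vri lay at 0.36, 0.23 and 0.05 and Clk at -0.43 in control heads, against -0.62, -0.45, -0.37 and 0.21 in knockout heads, opposite signs, which is not what a single shift shared by both genotypes would give. Fasting itself is the factor the design names, and time of day stays open beside it, since 0 of these folds passed.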

How the results depend on the processing

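The unshrunken folds, and the minimum fold combined with a base mean of at least 50, were chosen after seeing the data; the other alternatives were planned. Total counts of called genes moved by over 1.5 times only with a minimum change. With an absolute log2 fold of at least 1 they were 145, 181, 286 and 213 (control fasting, knockout fasting, fasted and fed knockout against control), which removes small changes by construction. Unshrunken folds exist only at a base mean of at least 50, and there the counts were 188, 191, 276 and 171 with an absolute unshrunken fold of at least 1, against 127, 149, 201 and 130 with the deposited folds of the same genes. By direction, a threshold of 0.01 left 27 in place of 50 falls in knockout fasting and 148 in place of 233 higher genes in fed knockout heads, which were 154 at a base mean of at least 50. With a t distribution with 6 degrees of freedom the difference between genotypes passed for 0 genes in place of 68; 190 had an unadjusted p under 0.05 and the smallest adjusted p was 0.108, since the heavier tails leave few p-values small enough. Over the other alternatives run for the difference it passed for 64 to 86 genes. That range is no independent check. A threshold of 0.1 can only add calls, and the other pair of tables holds the same 10 libraries. Its differences correlated with those used here at Pearson's r of 0.986 across 8430 genes. Genes that fell in both genotypes numbered 10 in place of 29 at a threshold of 0.01, since a stricter threshold keeps fewer. Of 112 list tests, 47 passed, and 34 did with a correlation of 0.05, 37 on ranks, 44 on folds and 42 at a base mean of at least 50; no called list changed direction. No paired analysis was possible because the tables hold no values per library. For the same reason leaving out each library, another count test, other size factors and other splits of the samples were not run, so whether 1 library decides a call is unknown.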

Other observations

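The purine synthesis genes were looked at as a group only after their values were seen. Of 8 genes (Prat, Prat2, Gart, Pfas, Paics, Adsl, CG11089 and ras), 6 rose in fasted control heads and 4 in fasted knockout heads, and 2 (Pfas and Adsl) differed between genotypes. Gart rose by 2.94 ± 0.17 in control and 2.63 ± 0.26 in knockout heads, and Paics by 2.12 ± 0.17 and 1.70 ± 0.27, in the authors' deposited tables. Pfas stood at 3.16 ± 0.15 and 0.56 ± 0.21, and Adsl at 1.72 ± 0.17 and 0.34 ± 0.24, in the authors' deposited tables. In fed heads 0 of the 8 were called between genotypes.

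Several lists or comparisons were not described above. Sugar and glycogen metabolism had 4 of 28 members higher and 0 lower in fasted knockout heads, and the same adjusted over the list alone (camera adjusted p = 4.93e-05). Odorant-binding proteins had 6 of 38 members higher and 2 lower in fasted knockout heads (adjusted over the list alone, 7 and 3; camera adjusted p = 0.547), with Obp57a at 2.48 ± 0.34 and Obp56e at 1.72 ± 0.33 in the authors' deposited table. Genes tied to Crtc activity, a list that holds Crtc itself, had 1 of 16 higher and 2 lower in fasted knockout heads (adjusted over the list alone, 2 and 5; camera adjusted p = 8.48e-05, and 0.272 on ranks), with CG14186 at -1.61 ± 0.19 in the authors' deposited table. Ecdysone and juvenile hormone genes had 3 of 21 higher and 1 lower there, and the same adjusted over the list alone (camera adjusted p = 0.961), with JhI-21 at -2.33 ± 0.22 and Jheh1 at 1.05 ± 0.20 in the authors' deposited table. In the same comparison eye pigment genes had 0 of 12 higher and w lower (adjusted over the list alone, 0 and 1; camera adjusted p = 0.516), and V-ATPase had Vha68-2 higher and 0 lower among 23 (adjusted over the list alone, 0 and 0; camera adjusted p = 0.716), a call of Vha68-2 that is lost with every gene with a p-value in the adjustment. Ribosome biogenesis had Non1 up in both fasting tables among 27 members, with 0 down and the same adjusted over the list alone (camera adjusted p = 0.938 in control and 0.547 in knockout heads). Oxidative phosphorylation had 0 of 82 called in fed heads between genotypes, and 0 adjusted over the list alone (camera adjusted p = 0.0401), a call lost with a correlation of 0.05 (adjusted p = 0.321), on folds (adjusted p = 0.173) and at a base mean of at least 50 (adjusted p = 0.0672). Female and male reproductive lists had 0 of 12 and 0 of 16 called in fasted control heads, and 0 adjusted over each list alone (camera adjusted p = 0.85 and 0.528).

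The fasting response of the clock list was not called to differ between genotypes (0 of 13 members called, 0 and 2 adjusted over the list alone, camera adjusted p = 0.0671). The signs of per, tim and vri against Clk were nevertheless opposite in control and knockout heads. A time of day that differed between the genotypes was therefore not separated from the difference of the fasting response. In fasted heads per was lower in knockouts at -0.72 ± 0.22, while Clk at 0.92 ± 0.27 and tim at 0.97 ± 0.19 were higher in the authors' deposited table. Of genes called alike in both knockout tables, 16 of 1593 tested genes (1%) were on the X chromosome, against 2.43% to 3.15% on the 4 large autosome arms. Control fasting also called a smaller share on the X, 2.57%, than on those arms (3.51% to 4.69%).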
